A study of Homo sapiens with 9 samples.

How the data were processed

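RNA of MDA-MB-231 cells was profiled on 9 one-colour Agilent arrays of design 028004, whose grid refers to genome build GRCh37, per the file headers. Per the labels' protocols, cells were grown in medium with fetal bovine serum, treated for 48 h with NLC-Citral, Citral or NLC-Blank diluted in fresh medium, and their total RNA was amplified and labelled with Cy3. Groups and replicate numbers were taken from the labels, 3 replicates in each of 3 groups. Per the file headers, the deposited files were made with Agilent Feature Extraction 11.5.1.1 from a G2600D scanner. They hold 1 spot intensity per probe and spot on a linear scale, background-subtracted and detrended within the array and not scaled between arrays. The authors' deposited value table also holds linear intensities, neither scaled between arrays nor centred: 8 of its 9 columns equal the processed signal of the same sample within 0.5%, with medians from 2.92 to 4.65, and the column of NLC-Blank replicate 1 does not (median 24.7, and 0.211% of 62973 values within 0.5%). The scale of that column stays unknown, so the table served only as an alternative.

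The files hold 58717 spots of 42405 probes besides 4259 control spots. They give no gene names, so probes were named through their RefSeq accessions in a table of assembly GRCh38.p14 genes without versions: 27231 probes had 1 symbol, 0 had several and 15174 had none, among them 1235 of 28466 probes with a RefSeq accession. No coordinates are printed because the builds differ. Control spots and outlier spots were left out, the log2 processed signals of repeated spots were averaged, and the 75th percentile of each file was subtracted. Because many probes were dim, the percentile was taken over the 8746 probes well above background on all 9 files. Probes well above background on at least 3 of the 9 files were kept (14416, of which 14298 had no missing value). A gene was represented by its probe with the highest mean signal over all files, which gave 12682 genes and transcripts, 8241 with a symbol. Where 1249 genes had a second kept probe, the fold changes of both probes correlated across genes at r = 0.214 to 0.395, so values of single probes are uncertain. Where a gene was not well above background on any array of a group, its fold is a lower bound, against the higher of the dimmest well-detected signal and its own signal on each array. All p-values named adjusted come from limma 3.58.1 in R 4.3.3, two-sided, with the Benjamini-Hochberg method and a threshold of 0.05.

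The headers give 6 array positions on 2 slides in 4 scans. Slide 2 held NLC-Citral replicate 1 and NLC-Blank replicate 3 and slide 1 the others. For 8 of the 9 files the position in the header differed from that in the file's name, and the sample records were followed. Scans at 1 header position with 1 label were averaged, which left 7 arrays where 9 had been planned, with 4 residual degrees of freedom, and 3 without NLC-Blank replicate 3. NLC-Citral replicate 1 and NLC-Blank replicate 3 share a header position too, in different scans. They were kept as 2 samples under their own labels. Their repeated-spot residuals correlated at r = 0.0229, but with a residual SD of 0.44 on the log2 scale in NLC-Blank replicate 3, against 0.06 to 0.11 on the other files, this cannot show whether they are 1 array or 2.

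The design and most alternatives were fixed before the data were examined. One limma model held all groups. The 38 fixed gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, over the 30 lists with at least 5 measured genes. With the estimated correlation 0 lists passed in any comparison, with smallest adjusted p of 0.495, 0.670 and 0.891 among 7 arrays and 0.160, 0.386 and 0.668 among 6. In fry, which tests only whether a list's genes move 1 way, 0, 4 and 2 lists passed among 7 arrays and 15, 13 and 10 among 6. Named genes were, for each comparison, those with the 10 highest and 10 lowest fold changes among calls with no overlap between groups and a symbol, up to 4 called members of each list or 2 with the smallest p, and 4 reference genes, of which HPRT1 was not measured above the filter. The rule was applied to the 7 and to the 6 arrays. Members given beside a list without calls are values only. Other splits of the samples were not counted because no comparison had 3 independent arrays in each group.

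The model was tested on simulated data, with 200 of 12682 genes changed in each of 10 runs at the measured spread. Among 7 arrays it recovered 41.1% of changes of 2 on the log2 scale in NLC-Citral against NLC-Blank, 37.4% in Citral against NLC-Blank and 28.2% in NLC-Citral against Citral, and 1.00%, 0.900% and 0.200% of changes of 1. Without NLC-Blank replicate 3 it recovered 61.4%, 59.3% and 58.9%, and 5.10%, 3.80% and 5.70%. In these simulations a change of 2-fold was therefore mostly missed. They changed fewer genes than passed in most comparisons and gave all arrays the same spread, so the share missed in the data may differ. Smaller changes did pass in the data: in Citral against NLC-Blank among 6 arrays 2370 of 3328 calls reached 2-fold. Alternatives were normexp with an offset of 50 on the median signal (the files hold no mean signal), quantile normalization, median scaling, other probe filters, outlier spots kept, the mean of all probes, the value table, 2 groups only, trend and robust moderation, array weights, the slide as a block, each replicate left out and a replicate block. Added after the data were examined were the percentile over all probes, the 9 files kept apart, 1 scan only, each rescanned array left out, and the alternatives repeated on 6 arrays. A change of scaling moved the median fold change of all genes by over 0.1 on the log2 scale: in Citral against NLC-Blank among 6 arrays it was 0.10, and -0.24 with the percentile over all probes. Fold changes are relative to the chosen scaling. Of 207 called values of named genes, over both sets of arrays, 126 moved by over 1.5 times with normexp on the median signal, and 0 with the other 3 scalings. The offset of 50 lies above the 75th percentile of the processed signal on each file (23.0 to 34.8). It therefore shrinks fold changes of dim genes by construction. The other 3 scalings reuse the same log2 signal and mainly shift whole arrays, so their 0 says little. The calls ended for 38 with normexp, 27 with quantile normalization, 5 with median scaling and 30 with the percentile over all probes, so fold changes and lower bounds hold for the processed signal only. Among the tested values that were compared between scalings only those of ACTB, TBP and ALDOC changed sign. Python 3.11.15 with pandas 2.3.3 prepared the tables and matplotlib 3.10.9 drew the figures.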

Results

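Gene expression was measured in MDA-MB-231 cells, a human breast cancer line, 48 h after treatment with NLC-Citral, Citral or NLC-Blank. Citral is a plant-derived mixture of the aldehydes geranial and neral. Each of the 3 groups had 3 labelled replicates, so 9 one-colour array files were read. Doses were not given in the sources used here, so whether the groups received the same amount of citral is unknown. The design text sets NLC-Citral against the control treatments, Citral or NLC-Blank, and Citral was also set against NLC-Blank to complete the 3 comparisons.

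Between 30.9% and 35.3% of spots were well above background on 8 of the 9 files, and 26.4% on the file labelled NLC-Blank replicate 3. Files NLC-Citral 2 and 3 shared 1 array position in their headers, as did files Citral 1 and 2, and their repeated-spot residuals correlated at r = 0.793 and 0.797 across spots, against -0.00978 to 0.584 for the 33 pairs at different positions. Each pair was therefore taken as 2 scans of a single array and counted as 1 sample, which left 7 independent arrays: 2 NLC-Citral, 2 Citral and 3 NLC-Blank. The array labelled NLC-Blank replicate 3 stood apart from the other NLC-Blank arrays. Its r across 12682 tested genes was 0.90 with each of NLC-Blank replicates 1 and 2, which correlated with each other at 0.990, and 0.955 with NLC-Citral replicate 1. Its repeated-spot SD was 0.44 on the log2 scale, against 0.06 to 0.11 on the other files, and its quality verdict was Evaluate where the other 8 were in range. Each count is therefore given for all 7 arrays and for the 6 arrays without it, a setting given this weight after the data were examined. The array was set apart partly for its likeness to NLC-Citral. Leaving it out therefore favours differences between NLC-Citral and NLC-Blank, and p-values of that comparison among 6 arrays are not calibrated. The array was also set apart for its noise, and all comparisons share 1 estimate of the spread. The p-values of the other comparisons among 6 arrays are therefore not calibrated either. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays, and their number limits the precision.

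**Figure D1:**
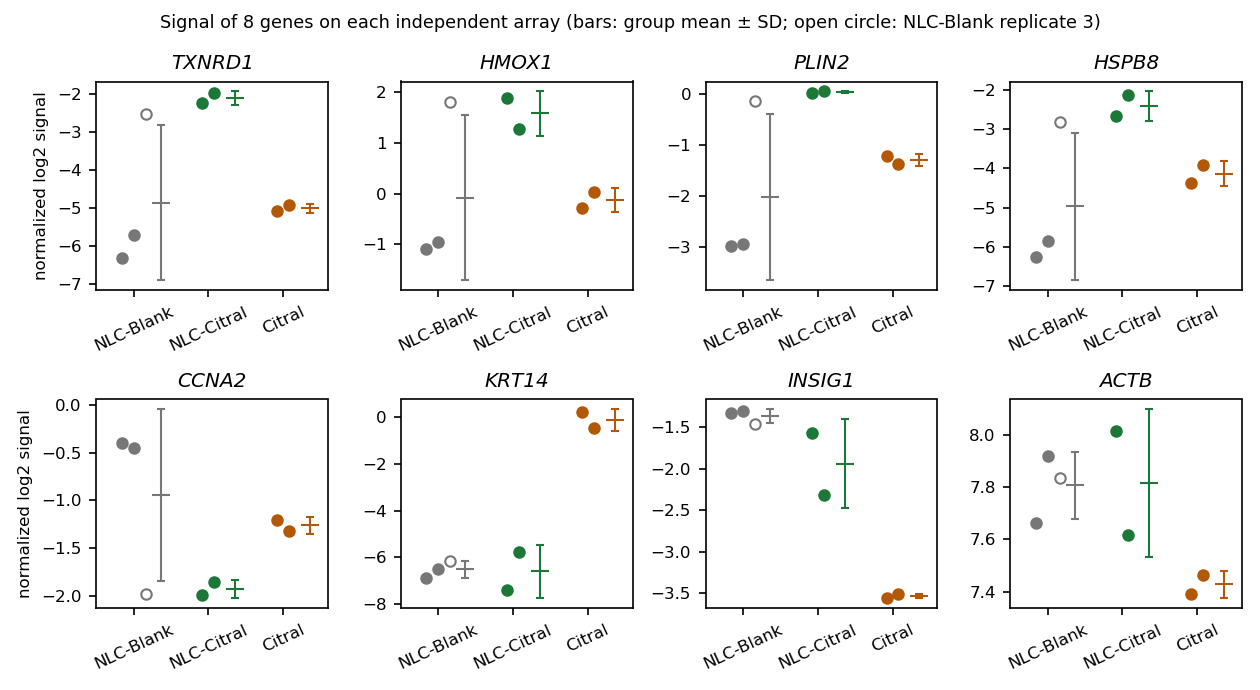
Normalized log2 signal of 8 genes (y axis) on each of the 7 independent arrays, by group (x axis), with the group mean and SD beside the points and the array labelled NLC-Blank replicate 3 as an open circle. For TXNRD1, HMOX1, PLIN2, HSPB8 and CCNA2 the open circle lies near the NLC-Citral arrays, while for KRT14 and INSIG1 it lies with the other NLC-Blank arrays. Both of these genes mainly set Citral apart, so they do not tell whether the array resembles NLC-Blank or NLC-Citral. KRT14 was well above background on 0 NLC-Citral and 0 NLC-Blank files. INSIG1 had log2 fold changes of -2.17 in Citral against NLC-Blank and 1.59 in NLC-Citral against Citral.

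NLC-Citral was set against NLC-Blank to ask what the loaded carrier changed beyond the blank one. Without the array labelled NLC-Blank replicate 3, 9 of 12 NRF2 target genes, 5 of 15 heat shock genes, 5 of 9 PPAR and lipid genes and 3 of 4 metallothionein and zinc genes rose in NLC-Citral cells. In the same cells 11 of 18 mitotic, 4 of 11 glycolysis and 3 of 5 fatty acid synthesis genes fell. The change was at least 15.2-fold upward for TXNRD1, thioredoxin reductase, and a log2 fold change of -1.50 ± 0.20 (SE) for CCNA2, cyclin A2. Of 12682 genes and transcripts, 1873 passed among these 6 arrays, 1204 higher (64.3%) and 669 lower, while 52.0% were higher after quantile normalization and 45.8% with the scaling percentile taken over all probes. With all 7 arrays 0 passed in limma, 652 had an unadjusted p under 0.05, and the smallest adjusted p was 0.586, so every rise or fall below refers to the 6 arrays. Their p-values rest on leaving out a control that resembled NLC-Citral, so they describe these arrays and are not calibrated. MAFK, a small partner of NRF2 at antioxidant elements, rose at least 50.4-fold (adjusted p = 0.000542). SLC22A7, an organic anion transporter, rose by a log2 fold change of 5.97 ± 0.28 (SE, adjusted p = 0.000356). RGS2, a regulator of G protein signalling, rose at least 14.9-fold and IL36A, an interleukin of the IL-1 family, at least 9.49-fold. COL8A1, a collagen chain, fell at least 26.8-fold, GJA1, the gap junction protein connexin 43, at least 14.9-fold, and ATP6V1B1, a proton pump subunit, at least 11.8-fold.

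Of 12 measured NRF2 target genes, 9 rose and 0 fell, and also 9 when adjusted over the list alone. TXNRD1 was among them with an adjusted p of 0.000542, and PRDX1, a peroxiredoxin, rose by 2.87 ± 0.20 on the log2 scale (SE, adjusted p = 0.000542). HMOX1, the heme-degrading enzyme, rose by 2.59 ± 0.27 (adjusted p = 0.00189) and FTH1, the ferritin heavy chain, by 2.44 ± 0.22 (adjusted p = 0.00114). In the camera test the list was higher than other genes among 6 arrays (adjusted p = 1.43e-06) and among 7 (adjusted p = 0.000482). With an estimated correlation the adjusted p was 0.160 and 0.495. Of 15 heat shock genes, 5 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0282 among 6 arrays, 0.119 among 7). The first of these was 0.444 as an adjusted p with an estimated correlation. HSPB8, a small heat shock protein, rose at least 12.5-fold, HSPA6, an inducible HSP70, by 3.03 ± 0.20 and CRYAB, another small chaperone, by 1.88 ± 0.20, while HSP90AB1, the constitutive HSP90, had a log2 fold change of -1.47 ± 0.26 (adjusted p = 0.0137).

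Of 9 measured genes of PPAR targets, fatty acid oxidation and lipid droplets, 5 rose and 1 fell, with 6 and 2 adjusted over the list alone, and the list itself did not pass (camera adjusted p = 0.0833), but did with normexp (0.00738, and adjusted p = 0.500 with an estimated correlation) and with the percentile over all probes (0.0377, and adjusted p = 0.416 with an estimated correlation). CD36, a fatty acid receptor, rose at least 5.46-fold, PLIN2, a lipid droplet coat protein, by 3.00 ± 0.20 on the log2 scale (SE, adjusted p = 0.000542) and CPT1A, the carnitine transferase of fatty acid oxidation, by 1.71 ± 0.21 (adjusted p = 0.00329). FABP3, a fatty acid binding protein, changed by -2.19 ± 0.21 (adjusted p = 0.00162). Among 5 fatty acid synthesis genes 3 fell, and 4 adjusted over the list alone (camera adjusted p = 0.0181, and adjusted p = 0.401 with an estimated correlation). SCD, the stearoyl-CoA desaturase, changed by -1.84 ± 0.20 (adjusted p = 0.00223). The other calls were less certain. SREBF1 changed by -1.10 (adjusted p = 0.0432), but its other probe by only -0.23. FASN changed by -0.93 (adjusted p = 0.0367), but with normexp by -0.19 (adjusted p = 0.490). Of 4 measured metallothionein and zinc genes, too few for a list test, 3 rose, and 3 adjusted over the list alone: MT1E by 1.79 ± 0.20, the zinc exporter SLC30A1 by 1.65 ± 0.22 and MT1X by 1.25 ± 0.19. Of 7 NF-kB and cytokine genes 3 rose, and 4 adjusted over the list alone (camera adjusted p = 0.0661, 0.0373 with the percentile over all probes, and there an adjusted p = 0.419 with an estimated correlation): IL6, an inflammatory cytokine, at least 4.19-fold, the NF-kB inhibitor NFKBIA by 1.52 ± 0.25 and RELB, an NF-kB subunit, by 1.33 ± 0.23.

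Of 18 G2/M and mitosis genes, 11 fell and 1 rose, with 15 and 1 adjusted over the list alone. CCNA2 was among them (adjusted p = 0.00449), and KIF20A, a mitotic kinesin, changed by -1.48 ± 0.23 on the log2 scale (SE, adjusted p = 0.00828). PLK1, a mitotic kinase, changed by -1.66 ± 0.27 (adjusted p = 0.00989), but its other probe by only -0.19. UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose at least 4.12-fold. The list was lower than other genes in camera among 6 arrays (adjusted p = 1.43e-06) and among 7 (adjusted p = 7.47e-07). With an estimated correlation the adjusted p was 0.160 and 0.495. Of 14 DNA replication and G1/S genes 4 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0267, and adjusted p = 0.465 with an estimated correlation). MCM7, a subunit of the replicative helicase, changed by -1.85 ± 0.28, and MCM2, another subunit, rose at least 3.67-fold. Of 11 glycolysis genes 4 fell, and 5 adjusted over the list alone (camera adjusted p = 0.0181, and adjusted p = 0.401 with an estimated correlation): TPI1, triosephosphate isomerase, by -2.48 ± 0.25, PGK1, phosphoglycerate kinase, by -2.33 ± 0.26 and GAPDH by -1.05 ± 0.25 among them. The remaining call, ALDOC at -1.42, was well above background on 0 NLC-Citral files and 1 NLC-Blank file. With normexp ALDOC had 0.08 (adjusted p = 0.796), so its fall is uncertain. Of 12 hypoxia genes 3 rose and 1 fell, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.0267, and adjusted p = 0.465 with an estimated correlation). ADM, the peptide adrenomedullin, rose at least 2.98-fold. The 19 ribosomal protein genes lay lower as a list (median -0.26, camera adjusted p = 0.0267, and adjusted p = 0.552 with an estimated correlation) with 0 single members past the threshold. Among 7 homologous recombination genes 1 fell, and 1 adjusted over the list alone (camera adjusted p = 0.0661, 0.0484 with the percentile over all probes, and there an adjusted p = 0.529 with an estimated correlation). With all 7 arrays the replication, homologous recombination and ribosomal lists were lower in camera (adjusted p = 0.0145, 0.0298 and 0.0303, each an adjusted p of 0.495 with an estimated correlation). Under normexp the calls of the hypoxia list among 6 arrays and of the homologous recombination and ribosomal lists among 7 ended (adjusted p = 0.113, 0.0554 and 0.217, the last also with the percentile over all probes, 0.0518), and under quantile normalization those of the ribosomal list among 6 arrays and of GAPDH did (adjusted p = 0.264 and 0.0682). ACTB, the actin reference gene, had a log2 fold change of 0.03 ± 0.23 and did not pass, and its other probe had 0.57.

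Within the slide and within the scan that hold all 3 groups, which also leave out NLC-Citral replicate 1, 808 and 775 passed.

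**Figure D2:**
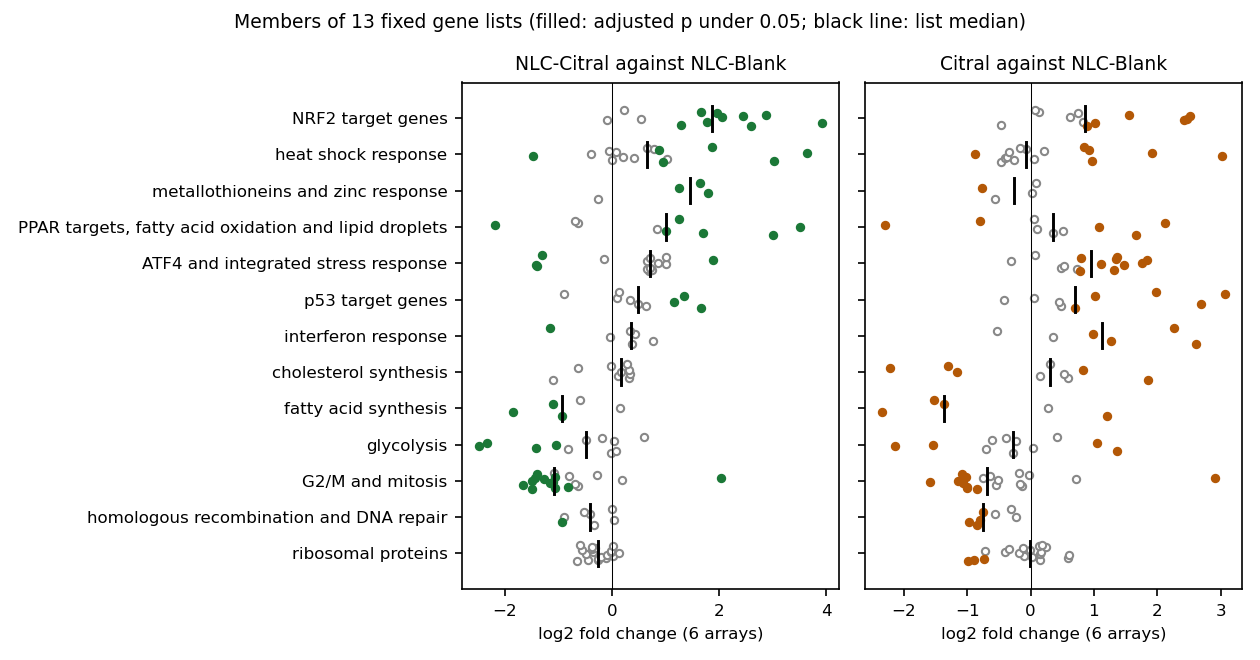
Log2 fold change (x axis) of each measured member of 13 fixed gene lists (y axis) among the 6 arrays without NLC-Blank replicate 3, for NLC-Citral (left) and Citral (right) against NLC-Blank. Filled points had an adjusted p under 0.05 in limma, and the black line is the list median, for example 1.86 for NRF2 target genes and -1.08 for G2/M and mitosis in NLC-Citral.

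Citral was set against NLC-Blank as the free compound against the blank carrier, so both the compound and the carrier differ. Citral cells had far higher signal of KRT14, KRT16P2 and KRT17. Among 7 arrays, 3 of 14 ATF4, 3 of 6 interferon and 3 of 9 p53 target genes rose, and 3 of 9 cholesterol synthesis genes fell. Of these lists only ATF4 passed in camera, and each ATF4 and interferon call ended under another scaling. Among the 6 arrays used for NLC-Citral, several NRF2 target genes also rose and several mitotic genes also fell in Citral, as given below. Among 7 arrays 1069 of 12682 genes and transcripts passed, 987 higher and 82 lower. Among the 6 arrays without NLC-Blank replicate 3, 3328 passed, 2457 higher (73.8%) and 871 lower, and all 1069 were among them. After quantile normalization 48.8% of the calls among 6 arrays were higher, and 38.9% with the percentile over all probes. KRT14, a basal keratin, was at least 69.0-fold higher (adjusted p = 0.00615), the keratin pseudogene KRT16P2 at least 47.1-fold higher (adjusted p = 0.0035), and KRT17, another basal keratin, rose by 5.23 ± 0.27 on the log2 scale (SE, adjusted p = 0.0035). These 3 are close relatives, and whether their probes tell them apart was not tested. ANKRD18DP rose by 6.73 ± 1.42 (adjusted p = 0.0361), the adhesion protein NLGN2 by 5.30 ± 0.99 and the amino acid transporter SLC38A7 by 5.22 ± 0.93. Of the genes that fell, CTNNA3, an alpha-catenin, changed by -2.75 ± 0.21 (adjusted p = 0.00581), CA6, a carbonic anhydrase, by -2.11 ± 0.40 and the growth factor binding protein IGFBP6 by -1.78 ± 0.33. The calls of ANKRD18DP, IGFBP6 and CA6 ended after quantile normalization (adjusted p = 0.051, 0.051 and 0.0708), those of IGFBP6 and CA6 also with the percentile over all probes (0.0807 and 0.0705), and that of CA6 with normexp (-0.70 on the log2 scale, adjusted p = 0.244).

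Of 8 keratinocyte and basal markers 4 were measured, and 3 of them rose, also 3 adjusted over the list alone: KRT14, KRT17 and SFN, the stratifin 14-3-3 protein, the last by 2.40 ± 0.31 on the log2 scale (SE, adjusted p = 0.0111). KRT5, the usual partner of KRT14, was not well above background on any Citral file. GATA3, a luminal transcription factor, rose by 3.40 ± 0.62 (adjusted p = 0.0247), the single one of 9 measured luminal markers that passed, also adjusted over the list alone (median -0.11, mean 0.24, camera adjusted p = 0.865). Other probes of the luminal marker KRT8, which were not tested, changed by 3.75 and -0.05 on the log2 scale. Of 14 ATF4 and integrated stress response genes 3 rose, and 7 adjusted over the list alone (camera adjusted p = 0.0261, and adjusted p = 0.670 with an estimated correlation). They were the transcription factor CEBPB (1.53 ± 0.31), CTH of cysteine synthesis (1.41 ± 0.21) and the mitochondrial folate enzyme ALDH1L2 (at least 2.00-fold). Of 6 interferon response genes 3 rose, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.148): the RNA sensor RIGI by 2.78 ± 0.52, the ubiquitin-like ISG15 by 2.40 ± 0.38 and OAS2, an oligoadenylate synthase, by 1.44 ± 0.32. Of 9 p53 target genes 3 rose, and 3 adjusted over the list alone (camera adjusted p = 0.180): the antiproliferative BTG2 by 3.20 ± 0.29, the pro-apoptotic BAX by 2.44 ± 0.33 (its other probe by 1.24) and the kinase PLK3 by 1.96 ± 0.24. Under all 4 other scalings the calls of ALDH1L2 and OAS2 ended, and with normexp both had log2 fold changes of 0.10 (adjusted p = 0.998 for both). Those of CTH, RIGI, CEBPB and GATA3 ended after quantile normalization (adjusted p = 0.0606, 0.0758, 0.0548 and 0.0708), those of CTH, RIGI and GATA3 also with the percentile over all probes (0.0904, 0.0845 and 0.0713), and with normexp those of CTH, ISG15 and BTG2 (0.87, 0.91 and 1.03 on the log2 scale, adjusted p = 0.137, 0.322 and 0.162). Among 6 arrays the p53 list passed (camera adjusted p = 0.0390, and adjusted p = 0.386 with an estimated correlation).

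Among 4 measured aryl hydrocarbon receptor targets, too few for a list test, 2 rose, also 2 adjusted over the list alone: the aldehyde dehydrogenase ALDH3A1 by 3.48 ± 0.27 on the log2 scale (SE, adjusted p = 0.00581) and TIPARP, a poly(ADP-ribose) polymerase, by 2.37 ± 0.36. ALDH3A1 was the single one of 8 aldehyde metabolism genes that passed, and 2 rose adjusted over the list alone (median -0.07, mean 0.38, camera adjusted p = 0.821). Of 12 NRF2 target genes 2 rose, also 2 adjusted over the list alone (camera adjusted p = 0.737), among them PGD, a dehydrogenase of the pentose phosphate pathway, at least 3.38-fold. Among 6 arrays 6 rose, and 9 adjusted over the list alone (camera adjusted p = 0.0224, and adjusted p = 0.386 with an estimated correlation), and 4 of these were not past the threshold with all 7. HMOX1 was among them, at 0.89 ± 0.27 against -0.05 ± 0.85 with 7 arrays, as was TXNRD1, at least 2.02-fold higher against -0.15 ± 1.04 on the log2 scale with 7. Both calls ended after quantile normalization (adjusted p = 0.0801 and 0.123) and with the percentile over all probes (0.146 and 0.0953), that of HMOX1 also with median scaling (0.0786) and that of TXNRD1 with normexp (0.160). The PGD call among 7 arrays ended with normexp (0.35 on the log2 scale, adjusted p = 0.906), after quantile normalization (0.0659) and with the percentile over all probes (0.0561), under which that of JUND ended too (0.0532). HSP90AB1 rose by 3.52 ± 0.50 (adjusted p = 0.0130), the single one of 15 heat shock genes that passed, also adjusted over the list alone, in a list whose median was -0.46 and mean 0.07. LAMP1, a lysosomal membrane protein, rose by 3.88 ± 0.29, with 3 of 15 autophagy and lysosome genes past the threshold, also 3 adjusted over the list alone (camera adjusted p = 0.394). Of 15 immediate early genes 2 rose, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.507): JUND, an AP-1 subunit, by 2.51 ± 0.35, and KLF6, a zinc finger factor, by 3.44 ± 0.41, although the other KLF6 probe changed by -0.53.

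Of 9 cholesterol synthesis genes 3 fell, with 3 lower and 2 higher adjusted over the list alone, in a list whose median was 0.23 and mean -0.07 (camera adjusted p = 0.609): INSIG1, a brake on sterol synthesis, changed by -2.17 ± 0.28 on the log2 scale (SE, adjusted p = 0.0108), ACAT2, an acetoacetyl-CoA synthesis enzyme, by -1.25 ± 0.22 and FDPS, farnesyl diphosphate synthase, by -1.21 ± 0.20. The 7 homologous recombination genes lay lower as a list (camera adjusted p = 0.0261, and adjusted p = 0.670 with an estimated correlation) with 0 members past the threshold and 2 adjusted over the list alone. This call ended with normexp, after quantile normalization and with the percentile over all probes (adjusted p = 0.0602, 0.0884 and 0.113). BRCA1 among them had -0.86 ± 0.23 (adjusted p = 0.0734). Of 18 G2/M genes 0 passed among 7 arrays, while among 6 arrays 8 fell and 1 rose, with 8 and 2 adjusted over the list alone (camera adjusted p = 0.00401, and adjusted p = 0.386 with an estimated correlation). The 15 endoplasmic reticulum chaperones were lower as a list among 6 arrays, with 4 lower and 1 higher, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.0203, adjusted p = 0.386 with an estimated correlation, and 0.0838 after quantile normalization). Of the reference genes, B2M rose by 1.46 ± 0.22 (adjusted p = 0.0154), while ACTB had -0.38 ± 0.23 and TBP -0.60 ± 0.22 and did not pass, and the other ACTB probe had 0.52. The calls of B2M, ACAT2 and FDPS ended with the percentile over all probes (adjusted p = 0.0805, 0.0694 and 0.0524), and the lower value of BRCA1 among 6 arrays did not pass with normexp (0.0839).

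Among the calls with a symbol and at least 2-fold higher signal, 67 had a second kept probe, of which 23 (34.3%) also reached 2-fold in the same direction, against 15.2% of the second probes of all genes. Within the slide and the scan that hold all 3 groups 4588 and 4416 passed, with the slide as a fixed and as a random block 2612 and 2705, and without the filter on dim probes 5. The count was 19 without the first Citral array, 109 without Citral replicate 3, 497 without either NLC-Citral array, and 550 and 510 without NLC-Blank replicates 1 and 2.

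**Figure D3:**
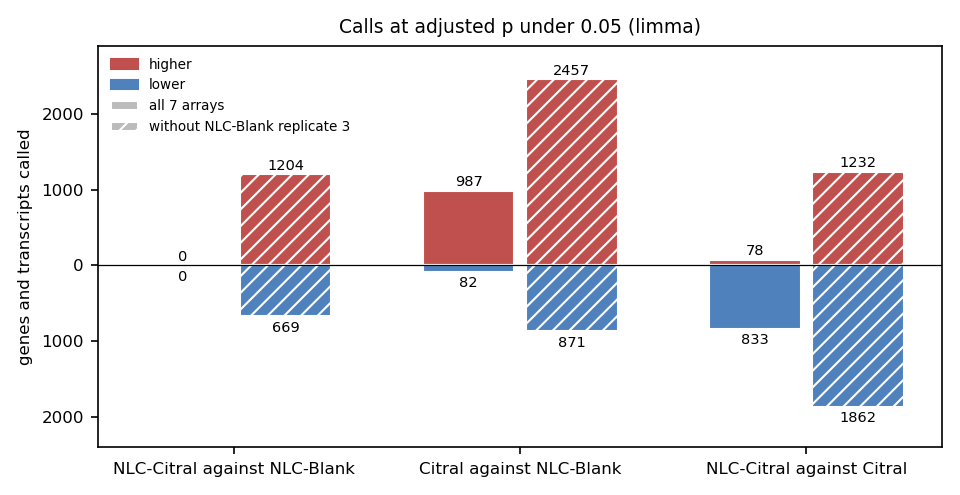
Number of genes and transcripts with an adjusted p under 0.05 in limma (y axis, higher above and lower below 0) in each comparison (x axis), for all 7 arrays (plain bars) and for the 6 arrays without NLC-Blank replicate 3 (hatched bars). NLC-Citral against NLC-Blank goes from 0 calls to 1204 higher and 669 lower.

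NLC-Citral was set against Citral to compare the loaded carrier with the free compound. Among 7 arrays 911 of 12682 genes and transcripts passed, 78 higher and 833 lower. Among 6 arrays 3094 passed, 1232 higher (39.8%, but 53.6% after quantile normalization, 56.9% with the percentile over all probes and 59.1% with detection on all 9 files) and 1862 lower, and all 911 were among them, since leaving out an NLC-Blank array changes only the estimate of the spread here. KRT14 was at least 68.8-fold lower (adjusted p = 0.00379), KRT16P2 at least 63.7-fold, KRT17 at least 52.7-fold, REC8, a meiotic cohesin subunit, at least 38.0-fold and BEX3, an adaptor of neurotrophin signalling, at least 37.4-fold. MT1B, a metallothionein outside the fixed lists, rose by 2.61 ± 0.55 on the log2 scale (SE, adjusted p = 0.0394), MYH7, a cardiac myosin chain, by 2.12 ± 0.40 (adjusted p = 0.0273), and LRRFIP1, a nucleic acid binding protein, at least 4.85-fold (adjusted p = 0.0118). With normexp the log2 fold change of LRRFIP1 was 0.46 and that of MYH7 1.22, and neither passed (adjusted p = 0.884 and 0.182), and the MT1B call ended after quantile normalization (0.064).

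Members of several lists were lower here that were higher in Citral against NLC-Blank. Both comparisons use the same Citral arrays with opposite sign, so part of this mirroring is built in. How much was not tested. Of 9 p53 target genes 3 fell, BTG2 at least 12.9-fold, with 3 lower and 1 higher adjusted over the list alone. The list's median fitted value was 0.15, its mean -0.56 and its camera adjusted p 0.682. Of 6 interferon response genes 2 fell, with 2 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.469): RIGI by -3.43 ± 0.57 on the log2 scale (SE, adjusted p = 0.0177) and ISG15 by -2.24 ± 0.41. Of 14 ATF4 genes 2 fell, also 2 adjusted over the list alone (camera adjusted p = 0.469): DDIT4, an mTOR inhibitor, by -2.89 ± 0.57 and CTH by -1.50 ± 0.23. ALDH3A1 changed by -3.63 ± 0.29, GATA3 by -4.56 ± 0.68, HSP90AB1 by -4.49 ± 0.55 and LAMP1 by -4.20 ± 0.32. Of 9 cholesterol synthesis genes 3 rose and 1 fell, the same adjusted over the list alone (median -0.04, mean 0.03, camera adjusted p = 0.617). Those that rose were INSIG1 by 1.59 ± 0.30, FDPS by 1.34 ± 0.22 and ACAT2 by 1.27 ± 0.24. Of 4 metallothionein and zinc genes 1 rose, MT1X by 2.01 ± 0.40 (adjusted p = 0.0312), and 3 adjusted over the list alone. Calls ended with normexp for BTG2, ISG15, CTH and INSIG1 (-1.24, -0.92, -0.97 and 0.93 on the log2 scale, adjusted p = 0.118, 0.393, 0.128 and 0.186), and for ACAT2 (0.054). They ended after quantile normalization for RIGI, DDIT4, CTH, INSIG1 and MT1X (adjusted p = 0.0637, 0.089, 0.0693, 0.058 and 0.0519), and with the percentile over all probes for RIGI, DDIT4, CTH, INSIG1 and ACAT2 (0.0581, 0.0856, 0.0891, 0.0585 and 0.0718).

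No list passed in camera among 7 arrays. Among 6 arrays the NRF2 list was higher in NLC-Citral, with 8 members that rose and 2 that fell, the same adjusted over the list alone (camera adjusted p = 0.0280, and adjusted p = 0.668 with an estimated correlation). TXNRD1 rose by 2.91 ± 0.26 on the log2 scale (SE, adjusted p = 0.000355), HMOX1 by 1.70 ± 0.27 and GCLC, of glutathione synthesis, by 1.74 ± 0.25. With all 7 arrays the same fold changes did not pass (adjusted p = 0.190, 0.324 and 0.128). The heat shock list was higher too, with 5 that rose and 1 that fell, and 8 and 1 adjusted over the list alone (camera adjusted p = 0.0280, and adjusted p = 0.668 with an estimated correlation). HSPA6 rose by 2.07 ± 0.20 and HSPB8 by 1.73 ± 0.29, and neither passed with all 7 arrays (adjusted p = 0.212 and 0.383). Both list calls ended after quantile normalization (adjusted p = 0.0703 for each) and with the percentile over all probes (0.0614 for each), and the heat shock call also with normexp (0.349).

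Without NLC-Citral replicate 1 the count was 0 in limma, with 1773 at an unadjusted p under 0.05. It was 134 without the second NLC-Citral array, 64 without the first Citral array and 253 without Citral replicate 3, while within the slide and the scan that hold all 3 groups, which also lack NLC-Citral replicate 1 and NLC-Blank replicate 3, 2245 and 2146 passed, and with the slide as a fixed and as a random block 1281 and 1552.

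Both comparisons against NLC-Blank share its arrays. With 7 arrays 0 genes passed the same way in both. With 6 arrays 865 did, 601 higher and 264 lower, and 226 passed in opposite directions. Independent lists of these sizes would share 233 higher and 45.9 lower. In 100 simulations of unchanged groups, with redrawn NLC-Blank values shared by both comparisons, the mean was 0. That mean was all but fixed, since almost no gene passes where no group differs. It cannot show how much of the 865 comes from the shared arrays. Across genes, which are not independent replicates, the fold changes correlated at r = 0.313, against 0.502 in the simulations, and their covariance was 0.237, against 0.0599, a difference of 0.178. With 7 arrays r was 0.0990 against 0.397, and the covariance 0.0522 against 0.107. The NLC-Blank arrays were too few to split, so part of the excess may come from the shared arrays. GSTA2, a glutathione transferase, rose in both, by 3.39 ± 0.24 in NLC-Citral and 4.36 ± 0.24 in Citral on the log2 scale (SE). TPI1 changed by -2.48 ± 0.25 and -2.14 ± 0.25, the histone gene H2AC1 by -2.50 ± 0.20 and -2.35 ± 0.20, and FABP3 by -2.19 ± 0.21 and -2.29 ± 0.21.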

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

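The tests in this part were all chosen after the results they bear on had been seen, apart from the share of second probes that were higher, which replaced an earlier test that could not decide. The keratinocyte test replaced 2 earlier ones that rested on marker counts, and the levels it uses had been seen.

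The deposited value column labelled NLC-Blank replicate 1, which the comparisons do not use, had a median of 24.7, above the 3.08 and 4.28 of the other 2 NLC-Blank columns. It was not another scaling of its own scanner file, since its r with that file was 0.665 across values. Nor were its values out of order, since spots of 1 probe had an SD of 0.138 on the log2 scale against 1.65 between probes. What stays open is an array of the same design with other RNA: its highest r with any scanner file was 0.688, below the lowest between any 2 of the files, 0.836, and its 10 spike-in probes followed its scanner file at r = 1.00. No biological explanation was tested, since the design names no further group.

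The array labelled NLC-Blank replicate 3 deviated from NLC-Blank replicate 1 the way NLC-Citral did. A noisy hybridisation of control RNA would give a slope near 0 on the deviation of the second NLC-Citral array from NLC-Blank replicate 2, and the slope was 0.836 ± 0.0117 (SE across genes), against 0.855 for NLC-Citral replicate 1 itself. A slide effect alone is argued against by a coefficient of 0.845 for that deviation once the difference between both NLC-Citral arrays was in the model. The difference itself had a coefficient of 0.858 ± 0.0135 (SE across genes). NLC-Blank replicate 3 thus also carried what set NLC-Citral replicate 1 apart from the second NLC-Citral array. Whether that is an effect of slide 2 or of NLC-Citral replicate 1 alone cannot be told apart here. RNA or an array of the NLC-Citral group under an NLC-Blank label stays a candidate explanation, since that 0.845 belongs to a difference measured within the other slide, and whether its file and that of NLC-Citral replicate 1, at 1 header position, come from 1 array stays open. No biological explanation was tested, since the arrays carry 1 label each, and the labels were not changed.

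The genes far higher on the Citral arrays were weighed next. A second kept probe existed for 67 of the calls at least 2-fold higher, with a median log2 fold change of 2.07. Of these second probes 34.3% (exact 95% interval 23.2% to 46.9%) reached 2-fold, against 15.2% of all. This argues against signal of single probes in every one of the 67 genes. It does not cover KRT14, KRT17 and SFN, which have 1 probe each. A slide difference is argued against by the layout, since both Citral arrays and NLC-Blank replicates 1 and 2 lay on slide 1. Within slide 1 alone 1068 of the 1069 genes called over both slides passed the same way. That count adds little, since most arrays behind the calls were these same ones. Whether keratinocytes in the cultures were the cause was not decided. KRT5 and KRT6A, abundant in such cells, lay at least 7.07 below KRT14 on the log2 scale on each Citral array. Both have 1 probe each, not well above background on any file. An absent transcript and a probe without signal therefore look alike, and levels of different probes are hard to compare. KRT14, KRT17 and SFN of the same list rose. Other cells as a source were not tested. For the 44 genes whose second probe did not reach 2-fold, single-probe signal cannot be told apart from a change in the transcript: 22 of these probes (50%) were higher (exact 95% interval 34.6% to 65.4%), against 44.1% of all second probes under 2-fold, and 44 are too few to separate these. A response of the cells to Citral stays open for the genes with 2 probes, as a hypothesis that no test here singles out.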

How the results depend on the processing

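Chosen after the data were examined were the percentile over all probes, the files kept apart, the single scan, each rescanned array left out, every setting on 6 arrays and the estimated correlation under other scalings.

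Among 7 arrays the counts in NLC-Citral against NLC-Blank, Citral against NLC-Blank and NLC-Citral against Citral were 0, 1069 and 911 genes and 5, 2 and 0 lists. Genes in NLC-Citral against NLC-Blank became 964 with array weights, 808 and 775 within the slide and the scan that hold all 3 groups, and 9 with 9 files kept apart. Leaving out single replicates gave 0 to 1873, the last without NLC-Blank replicate 3. For Citral against NLC-Blank and NLC-Citral against Citral, normexp gave 348 and 368, quantile normalization 392 and 426, no filter on dim probes 5 and 237, detection on all 9 files 466 and 334, the percentile over all probes 404 and 491, and the 2 groups alone 497 and 2589. Array weights gave 5240 and 2030, the slide as a random block 2705 and 1552 (as a fixed block 2612 in the first), the slide with all 3 groups 4588 and 2245, its scan 4416 and 2146, 9 files kept apart 3238 and 3254, and a replicate block on those files 2444 and 2455. Without the second NLC-Citral array 497 and 134 passed, without the first Citral array 19 and 64, and single replicates left out gave 109 to 3328 and 0 to 3094. The value table, whose NLC-Blank replicate 1 column stands apart, gave 0 in both with limma, with 697 and 735 at an unadjusted p under 0.05. Among 6 arrays the 3 counts were 687, 2044 and 1687 without the filter, 0, 3 and 0 with the value table and 970, 5053 and 1576 with array weights.

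Lists past the threshold in NLC-Citral against NLC-Blank became 8 with normexp, the percentile over all probes or the single scan, 9 with array weights or the single slide, 2 without the second NLC-Citral array and 3 to 8 without single replicates. In Citral against NLC-Blank they became 1 with quantile normalization, detection on all 9 files or the percentile over all probes, 6 with the value table, 4 with array weights or without the first Citral array, 5 within the slide, 7 within the scan and 0 to 6 without single replicates. In NLC-Citral against Citral they became 1 without the filter, 2 with the 2 groups alone and 0 to 2 without single replicates. With an estimated correlation 0 passed in each. The overlap of the NLC-Citral and Citral calls against NLC-Blank became 546 with array weights, 501 within the slide, 3 with 9 files kept apart, 483 within the scan and 0 to 865 without single replicates.

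In Citral against NLC-Blank, HMOX1 and TXNRD1 had negative values with all 7 arrays, which did not pass, and positive ones without NLC-Blank replicate 3: fitted values of 0.89 and 1.02 on the log2 scale within the slide, where the arrays compared are those same ones, and 0.90 and 0.97 within the scan. Without single replicates they ranged from -0.55 to 0.89 and from -0.89 to 1.02. No other gene value that was compared between settings passed with a sign opposite to that among all 7 arrays. Over all settings named genes lost the call 446 times and gained it 316 times, passed with the opposite sign in the 6 cases above, and without a call moved by at least 1 SE 73 times, 29 of them with the value table and 17 with normexp in NLC-Citral against NLC-Blank. The other 3311 times the call stayed, or none was made and the value moved by less. The lists kept their call or lack of it 2505 times, lost it 26 times and gained it 61 times, and no list called among 6 arrays changed direction under another scaling. Some lists lost their call under another scaling. In NLC-Citral against NLC-Blank these were, among 6 arrays, hypoxia with normexp (adjusted p = 0.113) and ribosomal proteins after quantile normalization (0.264), and among 7 arrays homologous recombination with normexp (0.0554) and ribosomal proteins with normexp (0.217) and the percentile over all probes (0.0518). In Citral against NLC-Blank they were, among 6 arrays, endoplasmic reticulum chaperones after quantile normalization (0.0838) and homologous recombination with normexp (0.0749), and among 7 arrays homologous recombination with normexp, quantile and the percentile over all probes (0.0602, 0.0884 and 0.113). In NLC-Citral against Citral among 6 arrays they were the NRF2 list (quantile 0.0703, percentile 0.0614) and the heat shock list (normexp 0.349, quantile 0.0703, percentile 0.0614). Other lists gained a call. In NLC-Citral against NLC-Blank these were, among 6 arrays, the PPAR list (normexp 0.00738, percentile 0.0377), and with normexp p53 targets, the TGF-beta response and reference genes (0.0162, 0.0388 and 0.0414), after quantile normalization proteasome subunits (0.0395), and with the percentile over all probes NF-kB and homologous recombination (0.0373 and 0.0484). Among 7 arrays they were heat shock (normexp 0.00974, percentile 0.0493), with normexp p53 targets, fatty acid synthesis, proteasome and autophagy (0.00478, 0.00833, 0.000105 and 0.0249), and ATF4, hypoxia and glycolysis after quantile normalization (0.0416, 0.0416 and 0.0227) and with the percentile over all probes (0.0392 each). In Citral against NLC-Blank they came with normexp: glycolysis and oxidative phosphorylation among 6 arrays (0.0267 and 0.0259), and endoplasmic reticulum chaperones and p53 targets among 7 (0.0474 each). With an estimated correlation no list passed under any of these scalings (smallest adjusted p = 0.0569 with an estimated correlation, NLC-Citral against NLC-Blank with normexp among 6 arrays). The cause of these changes was not tested, except that fewer arrays and fewer degrees of freedom follow from leaving arrays out. The normexp offset also shrinks fold changes of dim genes by construction. An array left alone in its group was taken to vary like the other groups. The planned replicate block could not be fitted on averaged arrays, and residuals of the same replicate number correlated at r = -0.365 to 0.311 between groups over 9 pairs, against -0.382 to 0.416 over 18 other pairs, so the numbers did not pair samples. Signal near background limits the dim genes: on the files 26.4% to 35.3% of spots were well above it.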

Other observations

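The lists in this part were fixed before the data were examined. The use of 6 arrays for NLC-Citral, without NLC-Blank replicate 3, was chosen afterwards, and the p-values there are not calibrated. The values for Citral come from 7 arrays and the marker counts from all 9 files.

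Further genes differed between NLC-Citral and NLC-Blank among these 6 arrays. Of 9 p53 target genes 3 rose, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0715, 0.0162 with normexp, and there an adjusted p = 0.399 with an estimated correlation). MDM2, the ubiquitin ligase that limits p53, rose by 1.67 ± 0.20 on the log2 scale (SE, adjusted p = 0.00299) and TP53INP1, a p53-induced nuclear protein, by 1.34 ± 0.21 (adjusted p = 0.00792). Of 15 immediate early genes 5 rose and 1 fell, with 7 and 2 adjusted over the list alone (camera adjusted p = 0.228). DUSP1, a phosphatase of MAP kinases, rose by 1.39 ± 0.22 and IER3, an early response gene, by 1.17 ± 0.20. Of 9 luminal epithelial markers 2 rose and 3 fell, with 3 and 4 adjusted over the list alone (median 0.24, mean -0.25, camera adjusted p = 0.570), and KRT18, a simple-epithelium keratin, changed by -2.29 ± 0.21 (adjusted p = 0.00119). Of 17 oxidative phosphorylation genes 0 passed in limma, also adjusted over the list alone (camera adjusted p = 0.230).

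In Citral against NLC-Blank 2 of 5 pro-apoptotic genes rose among 7 arrays, also 2 adjusted over the list alone (camera adjusted p = 0.388). Besides BAX, which the p53 list also holds, BCL2L11, a BH3-only killer protein, rose by 1.37 ± 0.32 on the log2 scale (SE, adjusted p = 0.0492), a call that ended under each other scaling, with 1.23 and an adjusted p of 0.196 for the percentile over all probes. Of 15 luminal epithelial markers 9 were well above background on all 3 Citral files, 7 on all NLC-Citral files and 6 on all NLC-Blank files. In the same order the counts were 5, 4 and 2 of 11 leukocyte markers and 4, 2 and 2 of 8 keratinocyte and basal markers. Of 10 fibroblast markers it was 1 in each group, and of 8 endothelial markers 1, 1 and 0. The groups are not alike here: the 3 files come from 2 arrays for Citral and NLC-Citral and from 3 for NLC-Blank. NLC-Blank replicate 3 had only 26.4% of spots well above background. ESR1, GATA3, CD3D, CD3E, CD14 and CDH5 were each above it on 2 NLC-Blank files, TFF3 and KRT17 on 1 and KRT14 on 0. PTPRC and CD79A were above it on all files of each group, so these counts alone do not show other cells.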
